A study of Mus musculus with 89 samples.

How the data were processed

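Total RNA of flash-frozen mouse livers and of primary hepatocytes was sequenced by the authors as stranded poly(A) libraries, in 89 samples of 23 groups. Per the submitters' processing notes the authors used bcl2fastq 2.19, TopHat2 2.0.11, Cufflinks 2.1.1 and DESeq2, with no version given for the last, and the mouse build mm9. The counting tool and the annotation were not stated. Of 42687 Ensembl identifiers in the 10 larger tables, 42329 are in GENCODE vM21, which belongs to the GRCm38 build, so the build named in the notes may not apply to these tables. Coordinates in the text are those of GENCODE vM21 on GRCm38, matched by gene.

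Deposited were 13 tables of the authors' own DESeq2 comparisons, 1 per treated group, and no counts. Per the file headers each holds a base mean, which is the mean count after scaling by size factors, a log2 fold change, its log2 standard error and a p-value with its Benjamini-Hochberg adjustment. A test score (Wald statistic) is a column of the authors' 3 tables keyed by RefSeq symbol, B16F10-Tb, 67NR-Tb and 4T1-Tb, and there the log2 fold change divided by its standard error equals the score. In the other 10 deposited tables, keyed by Ensembl identifier, the log2 fold changes were shrunken toward 0 by the authors while the p-values were not. There the value after ± is the deposited error of a shrunken fold. Base means were identical across the 3 particle classes and across both K7M2 EVP tables, so the authors fitted those groups together with shared controls. Library depth per sample is unknown, which limits the precision that can be stated to the authors' standard errors. The sums of base means given in the report are averages over the samples of each fit. Per-sample values being absent, no sample was left out or tested as an outlier, samples could not be regrouped, no replicate term was fitted, and overlap of the groups could not be checked for any gene. Genes with an adjusted p in a deposited table count as tested; the authors' filter left out genes of low base mean or with an extreme count.

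Groups were taken from the sample labels, and each treated group was compared with the PBS group of its own table. The rule followed for such tables, set before the data were examined, was to describe the authors' adjusted p and fold change with no new test per gene. The 33 gene lists, the rule for named genes, a panel of 25 genes and the 6 pairs of comparisons whose shared genes were counted were also fixed before the data were examined. Named genes are the 8 largest rises and 8 largest falls with an adjusted p under 0.05 and a base mean of at least 50, the 4 members of smallest p in each list, the panel, and the 5 largest differences each way between effects. Predicted genes were left out, and some genes that meet these criteria are not reported here. The lists hold 707 gene symbols, of which 702 were found in each format of table, after current and former symbols were matched. Where 1 symbol had several identifiers the best expressed was used, which concerned 90 entries.

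List tests were made with cameraPR of limma 3.58.1 in R 4.3.3 on the authors' scores, or on scores computed from the authors' p-values and the sign of the fold, for lists with at least 3 tested members. The planned test needs per-sample values, so this one was chosen after the format of the tables was seen. A preset correlation between genes of 0.01 was run first, and 0.05 was made the reported setting after the results were seen because it is stricter. An estimated correlation, which would show which calls hold with it, needs per-sample values and could not be had. Of 405 list tests 172 passed an adjusted p under 0.05, against 213 with 0.01 and 224 on ranks, and 170 of the 172 also passed on ranks. In 24 cases a list had too few members. In no list that passed did the median, the mean and the test differ in sign. In data simulated without any change for the B16F10-TE-EVPs comparison alone, 1 of 3100 lists passed, and 4 did with correlated genes. The simulated correlation equalled the preset of 0.05, so it cannot show how often more strongly correlated lists would pass.

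Differences between the effects of 7 pairs of groups were planned as a test on counts, not to be run on values normalised separately per table, so the tests made here in its place were chosen after the data were seen. Unshrunken effects and errors were recovered for the 10 shrunken tables by inverting a Cauchy prior whose width was fitted to each table. The difference of both effects was divided by its error and referred to a normal distribution, with adjustment over genes. No covariance was included for shared controls, which makes the errors too large for pairs that share them, so too few genes pass. On simulated data with the same kind of prior, 200 genes changed per pair by 1 or 2 log2, and between 181 and 202 were called with at most 12 wrong. That test is favourable, because its prior was known and its changes were large. By the shrunken folds, 20 genes rose and 0 fell by at least 1 log2 after B16F10-TE-EVPs. After B16F10-CL-EVPs 2 rose and 0 fell by as much. The simulation therefore does not show how many smaller differences would be found. In the real tables that share a fit, the ratio of errors recovered for the same gene had a median between 0.854 and 1.17 for genes with scores under 2 in both. For genes with scores above 4 in both it was 1.0 in the class pairs and 0.802 in the K7M2 pair (27 genes), so per-gene counts for shrunken pairs are approximate.

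Shared genes were counted with Fisher's exact test on genes tested in both tables, for the 6 planned and 9 added pairs, 15 in all. Values for shared controls without effects were simulated with a correlation of 0.5. Other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were an adjustment over every gene with a p-value, an adjusted p under 0.01 in both tables of an overlap, and, added after the data were seen, a base mean of at least 50, the deposited folds in place of recovered ones, recovered errors multiplied by 5/4, a correlation of 0.5 between effects with shared controls, and the other list test settings.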

Results

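Liver gene expression was measured by RNA sequencing in mice that carried tumours outside the liver, and in mice injected with tumour-derived extracellular vesicles and particles (EVPs). Primary hepatocytes exposed to tumour necrosis factor (TNF) were measured as well. The series held 89 samples in 23 groups. Every tumour or EVP group was set against mice given phosphate-buffered saline (PBS), with 9 PBS groups for the livers and 1 for the hepatocytes. The tumour lines were B16F10 and B16F1 melanoma in C57BL/6 mice, and K7M2 osteosarcoma and the 4T1 and 67NR mammary lines in BALB/c mice. B16F10, K7M2 and 4T1 are widely used metastatic lines, B16F1 is a less metastatic relative of B16F10, and 67NR forms mammary tumours that rarely spread. Melanoma cells were placed under the skin for 3 weeks, K7M2 cells in the tibia for 4 weeks, and mammary cells in the fat pad for 4 weeks. EVPs were given intravenously every other day for 4 weeks at 10 µg in 100 µl. TE-EVPs came from tumour explants and CL-EVPs from cultured cells, while exomeres, Exo-S and Exo-L were 3 size classes of B16F10 particles, from non-vesicular particles to small and large exosomes. Hepatocytes were exposed to TNF for 24 hours.

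The available measurements were 13 tables of the authors' own comparisons, each with 1 mean normalised count, log2 fold change, standard error and p-value per gene. Per-sample values and the depth of each library are unknown. The mean normalised counts in the authors' deposited tables summed to between 17755505, in the B16F1-Tb table, and 51511130, in the hepatocyte table. For a single comparison with PBS, numbers after ± are the standard errors in the authors' deposited tables, and adjusted p-values beside a gene are theirs as well. For a difference between the effects of 2 groups, both come from the test of the difference made here, with calls at an adjusted p under 0.05. A gene was taken as changed at an authors' adjusted p under 0.05. List tests used limma's cameraPR with a preset correlation of 0.05 between genes, adjusted over the lists of each comparison. Fold changes in 10 of the tables were shrunken by the authors and those of B16F10-Tb, 67NR-Tb and 4T1-Tb were not, so medians and folds of different tables are not strictly comparable.

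**Figure D1:**
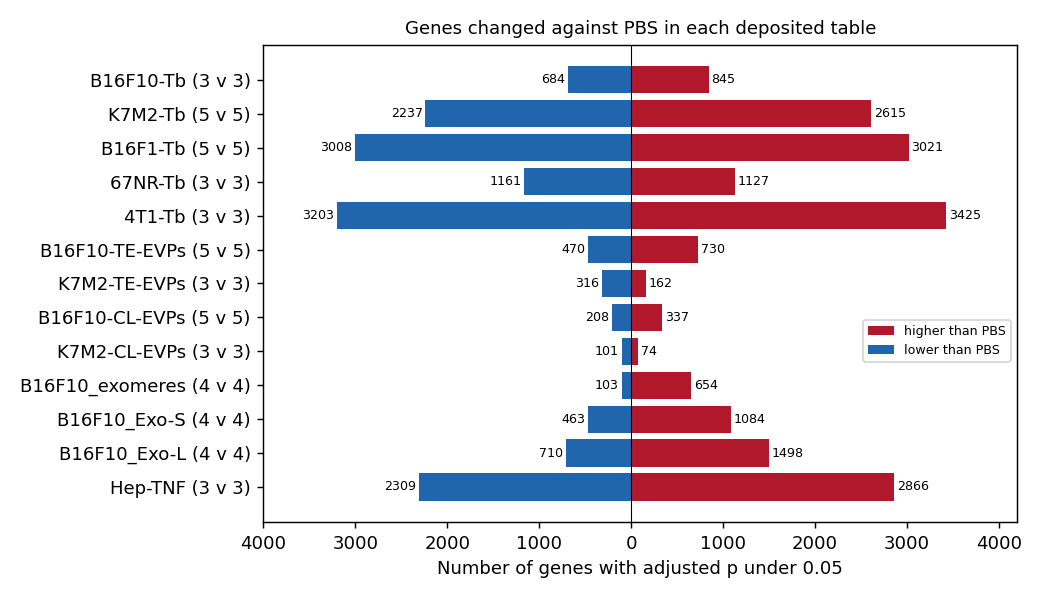
Number of genes that rose or fell at an adjusted p under 0.05 in each of the authors' 13 deposited tables, with 1 pair of bars per comparison and the number of genes on the horizontal axis. The counts ran from 175 genes for K7M2-CL-EVPs to 6628 for 4T1-Tb, with different numbers of mice per group (3 to 5).

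The comparison of B16F10-Tb with PBS-1, 3 livers each, asked whether a melanoma under the skin altered the liver. Genes of the acute phase response and of the cell cycle rose, and genes of lipid synthesis, drug metabolism and respiration fell. Slc41a2, a magnesium transporter on chromosome 10 (83230848 to 83337882), had the largest rise among the genes named here, 3.33 ± 0.25 log2 in the authors' deposited table (adjusted p = 2.82e-36). Apcs, which encodes serum amyloid P, rose by 2.68 ± 0.20 and Fgl1, a fibrinogen-like hepatokine, by 2.41 ± 0.18 in the authors' deposited table. Fgf21, a fasting and stress hormone made by the liver, rose by 2.18 ± 0.31 there. Acacb, an acetyl-CoA carboxylase, stood at −1.91 ± 0.22 and the caffeine-metabolising Cyp1a2 at −1.81 ± 0.22 in the same table of the authors.

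Of 26 acute phase genes tested in the authors' deposited table, 15 rose and none fell (18 rose when adjusted over the list alone; median 0.84 log2, list test adjusted p = 9.05e-12). Hp, which encodes haptoglobin, rose by 1.72 ± 0.18 and Lrg1 by 2.05 ± 0.26 in the authors' deposited table. Proliferation genes rose in 16 of 18 cases (16 adjusted over the list alone; median 1.52, adjusted p = 1.55e-14), among them the replication gene Mcm2 at 2.00 ± 0.27 and the mitotic kinase gene Aurka at 2.30 ± 0.29 in the authors' deposited table. Neutrophil markers rose in 8 of 12 cases (11 adjusted over the list alone; adjusted p = 3.11e-06), with S100a9 at 2.80 ± 0.31 in that deposited table of the authors. B cell markers rose in 4 of 9 cases (6 adjusted over the list alone; adjusted p = 2.83e-05), including the antigen receptor gene Cd79b at 1.62 ± 0.29 in the authors' deposited table. Immediate early genes rose in 8 of 14 cases and fell in 2 (11 and 2 adjusted over the list alone; adjusted p = 0.000519), with Atf3 at 1.53 ± 0.24 in the authors' deposited table.

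Lipogenesis genes fell in 12 of 19 cases in the authors' deposited table for B16F10-Tb (15 adjusted over the list alone; median −0.83, adjusted p = 5.34e-11). Elovl6, a fatty acid elongase, stood at −1.53 ± 0.22 and Thrsp at −1.71 ± 0.25 in the authors' deposited table. Cytochrome P450 genes of drug metabolism fell in 18 of 38 cases (1 rose and 20 fell when adjusted over the list alone; adjusted p = 9.05e-06), with Cyp2e1 at −1.19 ± 0.20 in the authors' deposited table. Oxidative phosphorylation genes fell in 21 of 75 cases (29 adjusted over the list alone; median −0.35, adjusted p = 4.61e-06), with the ATP synthase gene Atp5c1 at −0.63 ± 0.12 in the authors' deposited table. Gluconeogenesis and urea cycle genes fell in 11 of 20 cases and rose in 1 (12 and 1 adjusted over the list alone; adjusted p = 2.44e-05), with Ass1, argininosuccinate synthase, at −1.16 ± 0.20 in the authors' deposited table. Bile acid genes fell in 9 of 21 cases (11 adjusted over the list alone; adjusted p = 3.5e-05), including the bile acid importer gene Slc10a1 at −0.90 ± 0.16 in the authors' deposited table. In all, 845 of 13031 tested genes rose and 684 fell in the authors' deposited table.

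For K7M2-Tb against PBS-2, 5 livers each, the question was what an osteosarcoma in the bone did to the liver. Acute phase genes, interferon-stimulated genes and markers of neutrophils, macrophages and red cell precursors rose, and respiratory chain genes fell. Lcn2, which encodes the iron-siderophore binder lipocalin 2 on chromosome 2 (32384633 to 32388252), rose by 8.86 ± 0.20 log2 in the authors' deposited table, where its adjusted p is listed at 0. The neighbouring serum amyloid A genes Saa2 (ENSMUSG00000057465, chromosome 7, 46751790 to 46754313) and Saa1 stood at 8.81 ± 0.24 and 8.36 ± 0.21 in the authors' deposited table. The granule protease gene Prtn3 rose by 8.45 ± 0.42 and myeloperoxidase, Mpo, by 8.70 ± 0.59 in the authors' deposited table. Ces3b, a carboxylesterase gene, stood at −4.15 ± 0.28 and Hamp2, a hepcidin gene, at −3.52 ± 0.48 in the authors' deposited table.

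Acute phase genes rose in 26 of 28 cases and 1 fell in the authors' deposited table for K7M2-Tb (26 and 1 adjusted over the list alone; median 2.88, adjusted p = 5.18e-120). All 21 neutrophil markers tested rose (21 adjusted over the list alone; median 5.29, adjusted p = 3.54e-27), with S100a8 at 6.01 ± 0.31 in the authors' deposited table. Interferon-stimulated genes rose in 27 of 30 cases (28 adjusted over the list alone; adjusted p = 1.56e-15), among them Ifi44 at 2.71 ± 0.14 in the authors' deposited table. Kupffer cell markers rose in 14 of 15 cases (14 adjusted over the list alone; adjusted p = 1.45e-12), with the scavenger receptor gene Marco at 3.26 ± 0.25 in the authors' deposited table. Erythroid markers rose in 9 of 12 cases and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 1.9e-05), with the anion exchanger gene Slc4a1 at 4.62 ± 0.35 in the authors' deposited table. Proliferation genes rose in 22 of 23 cases (23 adjusted over the list alone; adjusted p = 2.52e-11), with Mki67 at 3.08 ± 0.26 in the authors' deposited table. Cholesterol synthesis genes rose in 17 of 24 cases and 1 fell (17 and 1 adjusted over the list alone; adjusted p = 0.000726), with squalene epoxidase, Sqle, at 3.36 ± 0.38 in the authors' deposited table.

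Genes of oxidative phosphorylation fell in 70 of 76 cases in the authors' deposited table for K7M2-Tb (72 adjusted over the list alone; median −0.51, adjusted p = 4.96e-11), with Ndufb8 at −0.61 ± 0.08. Fatty acid oxidation genes fell in 21 of 33 cases and 1 rose (22 and 1 adjusted over the list alone; adjusted p = 1.03e-06), with the peroxisomal thiolase gene Acaa1b at −2.46 ± 0.11 in the authors' deposited table. Phase II conjugation genes fell in 23 of 35 cases (23 adjusted over the list alone; adjusted p = 2.05e-05), with Gsta2 at −2.57 ± 0.24 in the authors' deposited table. Stellate cell and fibrosis genes fell in 11 of 18 cases and rose in 2 (13 and 2 adjusted over the list alone; adjusted p = 0.00161), with the collagen gene Col1a1 at −1.19 ± 0.21 in the authors' deposited table. The growth hormone receptor gene Ghr stood at −1.01 ± 0.10 and Igf1 at −0.62 ± 0.09, in a list with 4 falls and 1 rise among 11 genes in the authors' deposited table (4 and 1 adjusted over the list alone; adjusted p = 0.0494, but 0.109 on ranks). Osteoblast markers, which osteosarcoma cells can carry, had no rise or fall among 6 genes in the authors' deposited table and a list test adjusted p = 0.856. The authors' deposited table listed 2615 genes as higher and 2237 as lower among 17350 tested.

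B16F1-Tb livers were compared with PBS-4, 5 livers each, as the less metastatic melanoma. The hepcidin genes Hamp and Hamp2, of which Hamp encodes the hormone that limits iron uptake, fell steeply. Markers of red cell precursors and neutrophils rose. Hamp2 (ENSMUSG00000056978, chromosome 7, 30922372 to 30924681) stood at −12.41 ± 0.68 log2 and Hamp (30942368 to 30944032) at −11.02 ± 0.57 in the authors' deposited table (adjusted p = 1.13e-81 for Hamp). Fgf23, a phosphate-regulating hormone gene that erythropoietin can induce, rose by 11.08 ± 0.95 in the authors' deposited table. The erythroid gene Slc4a1 rose by 8.50 ± 0.94 in the authors' deposited table. Major urinary protein genes such as Mup17, at −7.12 ± 1.02, lay among the largest falls in the authors' deposited table, although reads shared within that family make single members uncertain.

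Erythroid markers rose in 10 of 12 cases in the authors' deposited table for B16F1-Tb and 1 fell (10 and 2 adjusted over the list alone; median 5.16, adjusted p = 1.45e-06), with the globin gene Hba-a1 at 4.77 ± 0.59. Neutrophil markers rose in 16 of 18 cases (17 adjusted over the list alone; adjusted p = 4.88e-10), with Prtn3 at 7.09 ± 0.63 in the authors' deposited table. Sinusoidal endothelial markers rose in 12 of 14 cases (12 adjusted over the list alone; adjusted p = 1.54e-07), with the scavenger receptor gene Stab2 at 1.81 ± 0.14 in the authors' deposited table. Markers of Kupffer cells rose in 14 of 15 cases (15 adjusted over the list alone; adjusted p = 6.44e-07), with the haem oxygenase gene Hmox1 at 1.91 ± 0.18 in the authors' deposited table. Acute phase genes rose in 19 of 28 cases and fell in 3 (19 and 3 adjusted over the list alone; adjusted p = 6.63e-07), with Hp at 2.15 ± 0.12 in the authors' deposited table. Interferon-stimulated genes fell in 22 of 30 cases (23 adjusted over the list alone; median −0.83, adjusted p = 6.16e-08), with the chemokine gene Cxcl9 at −3.06 ± 0.33 and Ifit1 at −2.44 ± 0.22 in the authors' deposited table. Oxidative phosphorylation genes fell in 64 of 76 cases (67 adjusted over the list alone; median −0.42, adjusted p = 4.57e-09), with Sdha at −0.64 ± 0.06 in the authors' deposited table. Phase II conjugation genes fell in 27 of 36 cases (28 adjusted over the list alone; adjusted p = 1.54e-07), with Ugt2b1 at −1.51 ± 0.18 in the authors' deposited table. The rate-limiting bile acid enzyme gene Cyp7a1 stood at −1.94 ± 0.21 and the lipid transport gene Apoa4 at 4.74 ± 0.21 in the authors' deposited table. Totals in the authors' deposited table were 3021 genes up and 3008 down among 17556 tested.

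The effects of B16F10 and B16F1 tumours were set against each other gene by gene. The effects on hepcidin and interferon-stimulated genes were higher in B16F10-Tb, and those on neutrophil, Kupffer cell and endothelial markers were higher in B16F1-Tb. Hepcidin did not rise in B16F10-Tb, with Hamp at −0.26 ± 0.21 (adjusted p = 0.48) and Hamp2 at −0.72 ± 0.24 (0.026) in the authors' deposited table. The effect on Hamp differed by 11.02 ± 0.61 log2 (adjusted p = 1.64e-68), with Fosb, an immediate early gene, at a difference of 6.49 ± 1.30, both recovered from the authors' deposited tables. Prtn3 differed by −5.62 ± 0.69 and Lcn2 by −3.42 ± 0.51, with the larger rise in B16F1-Tb, recovered from the authors' deposited tables. The interferon-stimulated list differed with adjusted p = 1.61e-14, the neutrophil list with 1.81e-06, the endothelial list with 1.31e-05 and the Kupffer list with 0.000875. By that test on effects from the authors' deposited tables, the effect passed as higher in B16F10-Tb for 564 of 12385 genes and in B16F1-Tb for 568, a total of 1132 that was 353 with the recovered errors multiplied by 5/4. Each line was studied in its own experiment with its own PBS group, so line and experiment cannot be told apart.

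With the rarely metastatic 67NR mammary tumour, 67NR-Tb against PBS-3 with 3 livers each, changes were many and small. Acute phase genes, endothelial markers and cholesterol synthesis genes rose, and respiratory chain and conjugation genes fell. Armcx4, on the X chromosome (134686519 to 134696757), rose by 1.41 ± 0.19 log2 in the authors' deposited table (adjusted p = 1.52e-10). Osmr, the oncostatin M receptor gene, rose by 1.13 ± 0.15 and Fgl1 by 1.11 ± 0.19 in the authors' deposited table. Cyp3a59 stood at −0.91 ± 0.12 and the glutathione transferase gene Gsta2 at −0.90 ± 0.16 in the authors' deposited table.

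Acute phase genes rose in 18 of 26 cases in the authors' deposited table for 67NR-Tb (20 adjusted over the list alone; median 0.52, adjusted p = 7.87e-07), with the fibrinogen gene Fga at 0.88 ± 0.13. Sinusoidal endothelial markers rose in 12 of 14 cases (13 adjusted over the list alone; adjusted p = 8.86e-07), with Kdr, a VEGF receptor gene, at 0.75 ± 0.16 in the authors' deposited table. Kupffer cell markers rose in 12 of 15 cases (13 adjusted over the list alone; adjusted p = 9.27e-06), with the haemoglobin scavenger gene Cd163 at 0.93 ± 0.17 in the authors' deposited table. Unfolded protein response genes rose in 9 of 16 cases and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.00071), with the chaperone gene Hspa5 at 0.42 ± 0.09 in the authors' deposited table. Cholesterol synthesis genes rose in 7 of 23 cases (7 adjusted over the list alone; adjusted p = 0.0237), with Cyp51 at 0.74 ± 0.11 in the authors' deposited table. Genes of oxidative phosphorylation fell in 45 of 75 cases (51 adjusted over the list alone; median −0.23, adjusted p = 5.44e-07), with Ndufa13 at −0.50 ± 0.09 in the authors' deposited table. Phase II genes fell in 17 of 33 cases (18 adjusted over the list alone; adjusted p = 3.25e-05), with Gstm1 at −0.58 ± 0.11 in the authors' deposited table. Neutrophil markers rose in 3 of 6 cases but the list test gave adjusted p = 0.158. By the authors' deposited table, there were 1127 rises and 1161 falls among 12329 tested genes, and 11 rises were of at least 1 log2 unit.

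In 4T1-Tb livers, compared with PBS-5 with 3 livers each, neutrophil granule genes and cell cycle genes rose and most genes of drug and fatty acid metabolism fell. Camp, which encodes the antimicrobial peptide cathelicidin on chromosome 9 (109847379 to 109849617), rose by 7.07 ± 0.38 log2 in the authors' deposited table (adjusted p = 1.09e-72). The alarmin gene S100a8 rose by 6.20 ± 0.40 and the chitinase-like gene Chi3l1 by 6.11 ± 0.37 in the authors' deposited table. Cyp4a10, a fatty acid hydroxylase gene, stood at −3.89 ± 0.34 and Vldlr, a lipoprotein receptor gene, at −2.69 ± 0.30 in the authors' deposited table.

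All 14 neutrophil markers tested rose in the authors' deposited table for 4T1-Tb (14 adjusted over the list alone; median 4.64, adjusted p = 1.84e-22). Proliferation genes rose in 23 of 23 cases (23 adjusted over the list alone; median 2.84, adjusted p = 2.53e-15), with Rrm2 at 3.67 ± 0.30 in the authors' deposited table. Monocyte markers rose in 13 of 14 cases (13 adjusted over the list alone; adjusted p = 7.48e-10), with lysozyme, Lyz2, at 2.80 ± 0.19 in the authors' deposited table. Acute phase genes rose in 25 of 27 cases (25 adjusted over the list alone; adjusted p = 3.21e-15), with Lcn2 at 5.17 ± 0.38 in the authors' deposited table. Stellate cell and fibrosis genes rose in 13 of 18 cases and 1 fell (13 and 1 adjusted over the list alone; adjusted p = 0.0116), with Col3a1 at 1.41 ± 0.23 in the authors' deposited table. Cytochrome P450 genes fell in 32 of 39 cases and 1 rose (32 and 1 adjusted over the list alone; median −1.06, adjusted p = 4.21e-08), with Cyp2a22 at −3.59 ± 0.22 in the authors' deposited table. Phase II genes fell in 32 of 35 cases and 1 rose (33 and 1 adjusted over the list alone; adjusted p = 1.87e-09), with the sulfotransferase gene Sult1c2 at −2.41 ± 0.20 in the authors' deposited table. Fatty acid oxidation genes fell in 29 of 33 cases and rose in 2 (29 and 2 adjusted over the list alone; adjusted p = 1.86e-07) in the authors' deposited table. Bile acid genes fell in 19 of 21 cases (19 adjusted over the list alone; adjusted p = 5.81e-07), with Slc10a1 at −1.35 ± 0.11 in the authors' deposited table. Oxidative phosphorylation genes fell in 69 of 75 cases (71 adjusted over the list alone; adjusted p = 6.69e-07), with Sdhb at −0.90 ± 0.12 in the authors' deposited table. Of all genes, 3425 rose and 3203 fell among 15272 tested in the authors' deposited table.

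The difference between the 4T1 and 67NR effects needed no recovery of fold changes, because neither table was shrunken. Acute phase, neutrophil and cell cycle genes had the larger effect in 4T1-Tb, and genes of fatty acid oxidation, lipid storage and drug metabolism the lower one. The effect on Saa2 was higher in 4T1-Tb by 4.37 ± 0.45 log2 (adjusted p = 1.69e-19), and that on the chromatin gene Hmgb2 by 3.76 ± 0.29, from the authors' deposited tables. Cyp4a10 differed by −3.98 ± 0.39 and the thioesterase gene Acot3 by −3.01 ± 0.45, computed from the authors' deposited tables. The proliferation list differed with adjusted p = 3.52e-16, the neutrophil list with 5.01e-12, the acute phase list with 4.44e-09 and the fatty acid oxidation list with 4.43e-08. In the test of the difference, on effects from the authors' deposited tables, 1895 of 12303 genes passed as higher and 2033 as lower in 4T1-Tb relative to 67NR-Tb, and the separate PBS groups leave line and experiment confounded.

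B16F10-TE-EVPs, the vesicles and particles of melanoma explants, were compared with PBS-6, 5 livers each, to ask whether EVPs alone act on the liver. Markers of macrophages and endothelial cells and a list of stellate cell and fibrosis genes rose, and genes of the respiratory chain fell by small amounts. Fyb, an adaptor gene of immune cells on chromosome 15 (6522853 to 6663313), rose by 1.26 ± 0.20 log2 in the authors' deposited table (adjusted p = 4.66e-08). Marco rose by 1.21 ± 0.42, Adgre1, which encodes the F4/80 macrophage antigen, by 1.11 ± 0.27 and the myeloid factor gene Spi1 by 1.03 ± 0.23 in the authors' deposited table. Gsta2 stood at −0.77 ± 0.27 and Etfb, an electron transfer flavoprotein gene, at −0.66 ± 0.11 in the authors' deposited table.

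Kupffer cell markers rose in 13 of 15 cases in the authors' deposited table for B16F10-TE-EVPs (13 adjusted over the list alone; median 0.80, adjusted p = 6.3e-12), with Csf1r at 0.98 ± 0.22 and C1qc at 0.93 ± 0.19. Monocyte markers rose in 5 of 10 cases (6 adjusted over the list alone; adjusted p = 5.81e-05), with Lyz2 at 0.84 ± 0.26 in the authors' deposited table. Endothelial markers rose in 7 of 14 cases (13 adjusted over the list alone; adjusted p = 1.39e-06), with the cadherin gene Cdh5 at 0.67 ± 0.20 in the authors' deposited table. Stellate cell and fibrosis genes rose in 7 of 17 cases (10 adjusted over the list alone; adjusted p = 1.74e-05), with Tgfb1, a profibrotic cytokine gene, at 0.97 ± 0.18 in the authors' deposited table. Genes of oxidative phosphorylation fell in 42 of 76 cases (55 adjusted over the list alone; median −0.18, adjusted p = 8.68e-14), with the complex I genes Ndufa3 at −0.42 ± 0.07 and Ndufv2 at −0.46 ± 0.08 in the authors' deposited table. Phase II genes fell in 6 of 35 cases (15 adjusted over the list alone; adjusted p = 0.000151), with Gstk1 at −0.28 ± 0.08 in the authors' deposited table. Cytochrome P450 genes fell in 3 of 39 cases (4 adjusted over the list alone; adjusted p = 0.0214), with Cyp3a11 at −0.31 ± 0.18 in the authors' deposited table. The acute phase list gave adjusted p = 0.632, with 1 of 28 members raised in the authors' deposited table. Altogether 730 genes rose and 470 fell among 13960 tested in the authors' deposited table.

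EVPs of cultured B16F10 cells, B16F10-CL-EVPs against PBS-8 with 5 livers each, also raised Kupffer cell markers and stellate cell genes. Upp2, a uridine phosphorylase gene on chromosome 2 (58567298 to 58792971), rose by 1.00 ± 0.20 log2 in the authors' deposited table (adjusted p = 1.07e-05). Birc5, which encodes the mitotic protein survivin, rose by 0.94 ± 0.22, and Lrat, a retinol-storing enzyme gene of stellate cells, by 0.78 ± 0.20 in the authors' deposited table. Smad7, an inhibitor of TGF-beta signalling, fell by 0.76 ± 0.28 in the authors' deposited table. Markers of Kupffer cells rose in 12 of 15 cases (13 adjusted over the list alone; median 0.50, adjusted p = 2.94e-10), with the macrophage gene Cd5l at 0.69 ± 0.20 in the authors' deposited table. Proliferation genes rose in 8 of 23 cases (8 adjusted over the list alone; adjusted p = 3.87e-06), with Top2a at 0.73 ± 0.24 in the authors' deposited table. Stellate cell genes rose in 7 of 17 cases (8 adjusted over the list alone; adjusted p = 0.000139), with Col3a1 at 0.57 ± 0.14 in the authors' deposited table. Oxidative phosphorylation genes had 1 fall among 76 in the authors' deposited table and a list test adjusted p = 0.105. The authors' deposited table gave 337 genes up and 208 down among 14426 tested, a total of 545 that was 347 when every gene with a p-value was included in the adjustment.

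Explant and cell-line EVPs of B16F10, an added pair, raised 151 genes in common in the authors' deposited tables, where independent lists would share 17.2. They lowered 2 in common, where 6.89 would be shared. Both preparations were then compared through the difference of their effects. Oxidative phosphorylation genes were lower after explant EVPs (adjusted p = 1.5e-06), as were phase II genes (7.98e-05) and cytochrome P450 genes (0.00424), and endothelial markers were higher (0.0331). These lists are the 4 of 8 that also differed with the folds as deposited by the authors. Upp2 differed by −1.69 ± 0.36 log2 (adjusted p = 0.00357) and Cyp2a5 by −1.45 ± 0.38, while the thyroxine-binding globulin gene Serpina7 differed by 1.52 ± 0.35, all recovered from the authors' deposited tables. Single genes depended on the recovery: 279 of 13824 differed, 169 of them higher after explant EVPs, but 148 did with every gene included. With the folds of the authors' deposited tables as given 8 differed, 2 of them higher and 6 lower after explant EVPs. With the recovered errors multiplied by 5/4, 0 differed in the normal test of the difference, beside 2167 at an unadjusted p under 0.05 in the reported setting, and preparation and experiment cannot be told apart.

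K7M2-TE-EVPs, from osteosarcoma explants, were compared with PBS-7 with 3 livers each. The inflammatory cytokine gene Il1b rose and genes of the respiratory chain and of lipid synthesis fell slightly. Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139) rose by 1.49 ± 0.31 log2 in the authors' deposited table (adjusted p = 1.39e-05). Cyp26a1, which breaks down retinoic acid, rose by 1.16 ± 0.43, and Pdk4, a kinase gene that restrains glucose oxidation, by 1.04 ± 0.50 in the authors' deposited table. The serine protease gene Prss8 stood at −1.58 ± 0.54 and Pdk2 at −0.51 ± 0.22 in the authors' deposited table. Oxidative phosphorylation genes fell in 10 of 76 cases (1 rose and 19 fell when adjusted over the list alone; median −0.09, adjusted p = 0.00969), with Ndufv1 at −0.32 ± 0.08 in the authors' deposited table. Lipogenesis genes fell in 3 of 19 cases (6 adjusted over the list alone; adjusted p = 0.00969), with Dgat2, which makes triglycerides, at −0.32 ± 0.09 in the authors' deposited table. TNF and NF-kB targets rose in 3 of 18 cases (5 adjusted over the list alone; adjusted p = 0.012), with Cebpd at 0.38 ± 0.35 in the authors' deposited table. The Kupffer cell list passed its test (adjusted p = 0.00969; median 0.13) although none of its 15 members passed alone in the authors' deposited table, where Vsig4 stood at 0.21 ± 0.13 (1 rose when adjusted over the list alone). Among 11820 tested genes 162 rose and 316 fell in the authors' deposited table, a total of 478 that was 275 when every gene with a p-value was included in the adjustment.

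K7M2-CL-EVPs shared the PBS-7 controls, with 3 livers each. The immunoglobulin constant region gene Ighg1, on chromosome 12 (113325240 to 113330523), rose by 4.02 ± 0.37 log2 in the authors' deposited table (adjusted p = 1.91e-23). Whether 1 of the 3 mice decides this rise cannot be seen without per-sample values. The phospholipid flippase gene Atp11a rose by 1.22 ± 0.20 and Il1b by 1.06 ± 0.31 in the authors' deposited table. Cyp2a22 stood at −0.77 ± 0.15 and the clock repressor gene Nr1d1 at −0.81 ± 0.41 in the authors' deposited table. Acute phase genes rose in 4 of 28 cases (14 adjusted over the list alone; median 0.05, adjusted p = 8.38e-08), with the fibrinogen genes Fga at 0.71 ± 0.23 and Fgg at 0.69 ± 0.23 in the authors' deposited table. Unfolded protein response genes rose in 3 of 16 cases and 1 fell (8 and 2 adjusted over the list alone; adjusted p = 0.00159), with Dnajc3 at 0.29 ± 0.10 in the authors' deposited table. Genes of oxidative phosphorylation fell in 2 of 76 cases (4 adjusted over the list alone; adjusted p = 8e-05), with Ndufs3 at −0.20 ± 0.08 in the authors' deposited table. The authors' deposited table held 74 genes up and 101 down among 11820 tested.

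Between explant and cell-line EVPs of K7M2, Ighg1 was the main gene to differ, at −3.08 ± 0.45 log2 (adjusted p = 1.3e-07) as recovered from the authors' deposited tables, and again 1 mouse may decide it. The other was Zfp36l1-ps, a pseudogene, at −0.98 ± 0.22, so that 2 of 11820 genes differed, beside 222 at an unadjusted p under 0.05 in the same test of the difference, made on effects from the authors' deposited tables. That setting left out the covariance from the shared PBS-7 livers, which makes its errors too large and its count too low. With a correlation of 0.5 between the effects, 29 differed, 20 of them higher and 9 lower after explant EVPs. The immediate early list differed with adjusted p = 0.0102, a call that was lost with the folds as deposited by the authors. Both effects rest on the PBS-7 livers, and their correlation across genes, recovered from the authors' deposited tables, was 0.631, beside 0.482 in simulated data with shared controls and no effect. In both, 32 genes rose and 45 fell in the authors' deposited tables, where independent lists would share 1.01 and 2.70 and the simulation had 0 genes called in both. Part of this excess may still come from the shared controls, which cannot be divided without per-sample values.

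The 3 particle classes of B16F10 were each compared with PBS-10, 4 livers each, to ask which class acts on the liver. Serum amyloid A genes, interferon-stimulated genes and macrophage markers rose in all 3 comparisons. After exomeres, Saa2 rose by 4.23 ± 0.29 log2, Marco (ENSMUSG00000026390, chromosome 1, 120474538 to 120505024) by 3.69 ± 0.19 and the interferon-induced GTPase gene Tgtp1 by 4.14 ± 0.41 in the authors' deposited table. Interferon-stimulated genes rose in 22 of 30 cases after exomeres (25 adjusted over the list alone; median 0.89, adjusted p = 5.83e-25), with Cxcl9 at 2.76 ± 0.24 in the authors' deposited table. The interferon-stimulated Isg15 stood at 0.11 ± 0.20 after exomeres in the authors' deposited table (adjusted p = 0.31). Kupffer cell markers rose in 11 of 15 cases (13 adjusted over the list alone; adjusted p = 2.19e-34) and T and NK cell markers in 9 of 17 (14 adjusted over the list alone; adjusted p = 2.95e-11) in the authors' deposited table. Acute phase genes rose in 9 of 28 cases (9 adjusted over the list alone; median 0.01, adjusted p = 1.57e-05, but 0.271 on ranks), with Orm2, an orosomucoid gene, at 1.92 ± 0.24 in the authors' deposited table. Fatty acid oxidation genes fell in 4 of 33 cases (9 adjusted over the list alone; adjusted p = 0.00218), with Cyp4a14 at −0.79 ± 0.26 in the authors' deposited table. After exomeres 654 genes rose and 103 fell among 15362 tested in the authors' deposited table.

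After Exo-S, the small exosomes, Tgtp1 rose by 6.25 ± 0.41 log2 and Saa3 (chromosome 7, 46711998 to 46715700) by 4.98 ± 0.21 in the authors' deposited table (adjusted p = 1.07e-116 for Saa3). Lcn2 rose by 4.29 ± 0.46 and Hao2, a hydroxyacid oxidase gene, fell by 1.52 ± 0.35 in the authors' deposited table. Interferon-stimulated genes rose in 26 of 30 cases (27 adjusted over the list alone; median 1.48, adjusted p = 8.47e-49), with the guanylate-binding protein gene Gbp2 at 4.23 ± 0.29 in the authors' deposited table. Monocyte markers rose in 11 of 14 cases (12 rose and 1 fell when adjusted over the list alone; adjusted p = 7.09e-15), with the chemokine receptor gene Ccr2 at 1.68 ± 0.21 in the authors' deposited table. Proliferation genes rose in 12 of 23 cases (15 adjusted over the list alone; adjusted p = 1.59e-06), with Mcm5 at 1.72 ± 0.18 in the authors' deposited table. TNF and NF-kB targets rose in 9 of 22 cases and 1 fell (13 and 1 adjusted over the list alone; adjusted p = 0.000115), with Tnf itself at 1.40 ± 0.56 in the authors' deposited table. Cytochrome P450 genes fell in 11 of 39 cases (11 adjusted over the list alone; adjusted p = 5.5e-05), with Cyp2c37 at −0.65 ± 0.11 in the authors' deposited table. Oxidative phosphorylation genes fell in 23 of 76 cases (36 adjusted over the list alone; adjusted p = 8.4e-06), with Sdha at −0.18 ± 0.05 in the authors' deposited table. Of 15852 tested genes 1084 rose and 463 fell in the authors' deposited table.

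Exo-L, the large exosomes, raised Saa3 by 5.40 ± 0.21 log2 and Marco by 4.59 ± 0.19 in the authors' deposited table (adjusted p = 8.04e-137 for Saa3). Acod1, which makes itaconate in macrophages, rose by 4.56 ± 0.49, and the stress cytokine gene Gdf15 fell by 1.52 ± 0.37 in the authors' deposited table. Kupffer cell markers rose in 13 of 15 cases (13 adjusted over the list alone; median 1.26, adjusted p = 4.46e-36) and interferon-stimulated genes in 25 of 30 (26 adjusted over the list alone; adjusted p = 4.84e-26) in the authors' deposited table. T and NK cell markers rose in 14 of 17 cases (15 adjusted over the list alone; adjusted p = 3.08e-12), with the chemokine gene Ccl5 at 2.58 ± 0.23 and the granzyme gene Gzmb at 2.06 ± 0.29 in the authors' deposited table. Stellate cell and fibrosis genes rose in 6 of 18 cases and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.0057), with Col1a1 at 1.40 ± 0.13 in the authors' deposited table. Fatty acid oxidation genes fell in 19 of 33 cases (1 rose and 23 fell when adjusted over the list alone; median −0.23, adjusted p = 3.78e-06), with Acadm at −0.46 ± 0.10 in the authors' deposited table. Genes of oxidative phosphorylation fell in 42 of 76 cases (56 adjusted over the list alone; adjusted p = 1.01e-06), with the ATP synthase gene Atp5g1 at −0.25 ± 0.07 in the authors' deposited table. Hepatocyte identity genes fell in 12 of 21 cases and 1 rose (13 and 1 adjusted over the list alone; adjusted p = 8.95e-05), with albumin, Alb, at −0.55 ± 0.12 in the authors' deposited table. The authors' deposited table gave 1498 genes up and 710 down among 17322 tested.

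**Figure D2:**
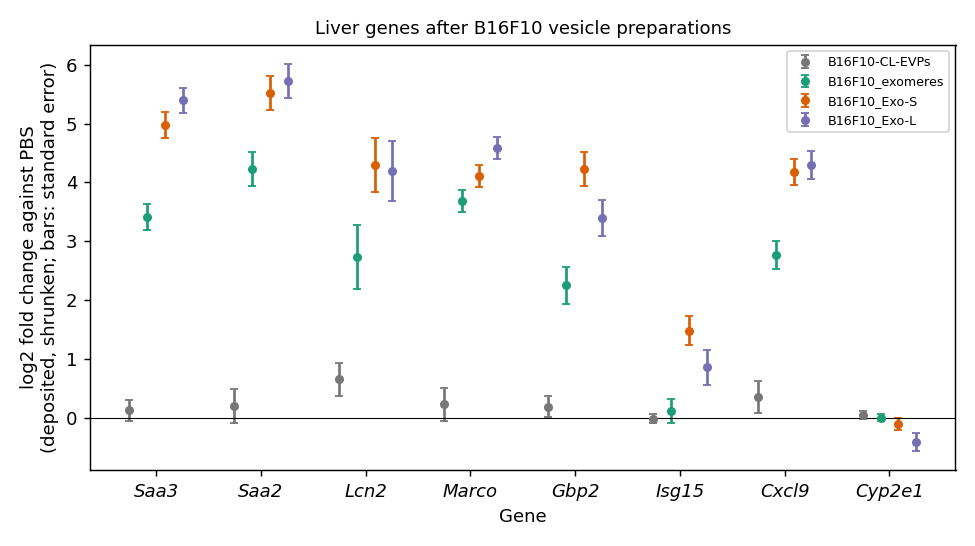
Log2 fold change with its standard error, on the vertical axis, of 8 genes after B16F10-CL-EVPs, exomeres, Exo-S and Exo-L, as deposited by the authors with shrunken folds. B16F10-CL-EVPs were compared with PBS-8 and the 3 classes with PBS-10, normalised separately, and Saa3 stands at 3.42 after exomeres, 4.98 after Exo-S and 5.40 after Exo-L.

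Differences among the 3 classes were tested through the difference of their recovered effects, without the covariance that the shared PBS-10 livers bring. Leaving it out makes the errors too large. A small number of differing genes therefore does not show that 2 classes acted alike. Interferon-stimulated genes were lower after exomeres than after Exo-S (adjusted p = 2.57e-22) and higher after Exo-S than after Exo-L (9.97e-05). Kupffer cell markers were lower after Exo-S than after Exo-L (adjusted p = 2.88e-19), and T and NK cell markers were as well (3.95e-06). Isg15 differed by −1.27 ± 0.28 log2 between exomeres and Exo-S (adjusted p = 0.00708) and Gbp2 by −1.86 ± 0.42 (0.00961), recovered from the authors' deposited tables. Saa3 was lower after exomeres than after Exo-L by a difference of −2.02 ± 0.31 (adjusted p = 6.92e-07), and Csf1r lower after Exo-S than after Exo-L at −0.74 ± 0.16 (0.0284), recovered from the authors' deposited tables. In counts, 46 of 15360 genes differed between exomeres and Exo-S, 27 of 15360 between exomeres and Exo-L, and 5 of 15849 between Exo-S and Exo-L, from the authors' deposited tables. With the recovered errors multiplied by 5/4 these counts were 1, 1 and 0 in the normal test of the difference, the last beside 648 genes at an unadjusted p under 0.05 in the reported setting, and with a correlation of 0.5 between the effects they were 348, 797 and 249.

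The recovered effects of the classes, which share PBS-10, were correlated across genes at 0.825, 0.831 and 0.852, from the authors' deposited tables, where simulated shared controls without effects gave 0.491, 0.483 and 0.492. Genes that rose in both numbered 585 for exomeres and Exo-S, 636 for exomeres and Exo-L and 947 for Exo-S and Exo-L in the authors' deposited tables. Independent lists would share 46.0, 62.7 and 101 of them, and the simulation had 5, 6 and 3 genes called in both. The control livers cannot be divided without per-sample values, so part of the excess may come from the shared PBS-10 livers.

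Primary hepatocytes given TNF were compared with hepatocytes given PBS, 3 cultures each, to ask what this cytokine does to the cells. Targets of NF-kB rose, and genes of the urea cycle, of bile acid handling and of hepatocyte identity fell. Traf1, a TNF receptor adaptor gene on chromosome 2 (34941750 to 34961772), rose by 5.11 ± 0.31 log2 in the authors' deposited table (adjusted p = 1.62e-59). The chemokine genes Cxcl3 and Ccl2 rose by 4.85 ± 0.22 and 3.89 ± 0.08 and the nitric oxide synthase gene Nos2 by 3.94 ± 0.29 in the authors' deposited table. Vsig4, a complement receptor gene of Kupffer cells, stood at −4.68 ± 0.43 and the urea cycle gene Cps1 at −3.14 ± 0.10 in the authors' deposited table.

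TNF and NF-kB targets rose in 23 of 25 cases and 1 fell in the authors' deposited hepatocyte table (23 and 1 adjusted over the list alone; median 1.71, adjusted p = 1.25e-58), with Vcam1 at 3.73 ± 0.08 and Tnfaip3 at 2.32 ± 0.06. Interferon-stimulated genes rose in 21 of 30 cases and fell in 2 (22 and 2 adjusted over the list alone; adjusted p = 8.63e-05), with Gbp2 at 1.41 ± 0.08 in the authors' deposited table. Gluconeogenesis and urea cycle genes fell in 19 of 20 cases (19 adjusted over the list alone; median −0.74, adjusted p = 4.46e-19), with arginase, Arg1, at −2.30 ± 0.11 in the authors' deposited table. Hepatocyte identity genes fell in 20 of 21 cases (20 adjusted over the list alone; adjusted p = 2.06e-15), with the fetuin gene Ahsg at −1.27 ± 0.05 in the authors' deposited table. Cytochrome P450 genes fell in 33 of 39 cases (34 adjusted over the list alone; adjusted p = 5.22e-06), and bile acid genes in 14 of 20 (15 adjusted over the list alone; adjusted p = 7.61e-07) in the authors' deposited table. Baat, which conjugates bile acids, stood at −2.23 ± 0.15 in the authors' deposited table. Acute phase genes went both ways, with 4 up and 15 down among 28 in the authors' deposited table (4 and 16 adjusted over the list alone; adjusted p = 0.0812). Saa3 stood at 2.01 ± 0.09, fibrinogen Fga at −0.91 ± 0.07 and Lcn2 at 0.02 ± 0.05 (adjusted p = 0.75) in the authors' deposited table. Oxidative phosphorylation genes fell in 30 of 76 cases (33 adjusted over the list alone; median −0.12, adjusted p = 0.0283), with Ndufa6 at −0.54 ± 0.07 in the authors' deposited table. Transcripts of Kupffer cells were present in the cultures and moved both ways, with 3 up and 9 down among 15 in the authors' deposited table (3 and 9 adjusted over the list alone; adjusted p = 0.139) and Marco at 1.33 ± 0.10. Counts in the authors' deposited table were 2866 genes up and 2309 down among 17488 tested.

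**Figure D3:**
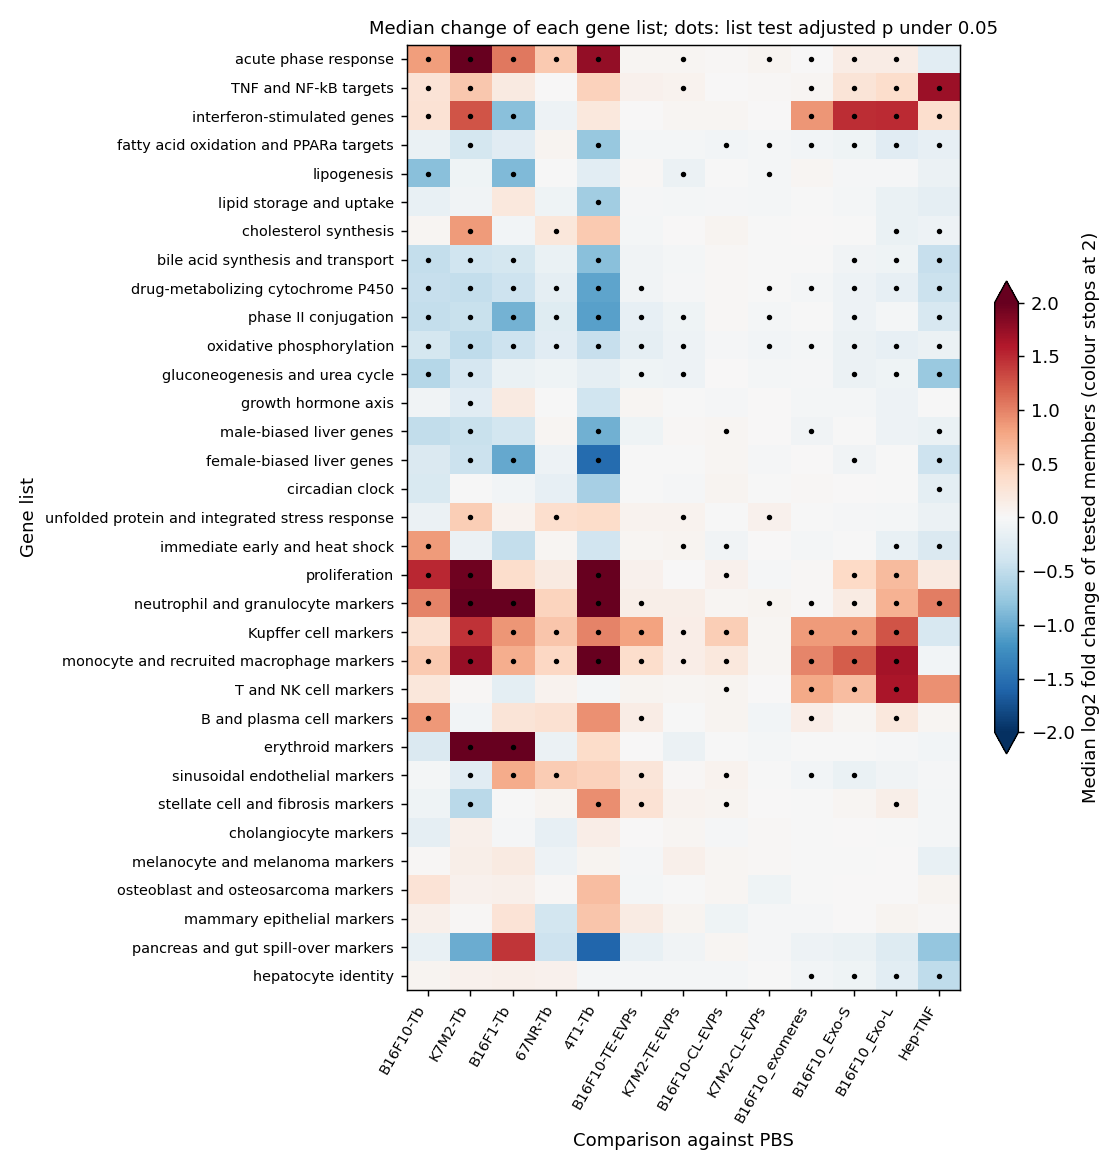
Median log2 fold change of 33 gene lists (vertical axis) in the 13 comparisons (horizontal axis), from the authors' deposited fold changes, as a colour scale that stops at 2 log2 units either way. Dots mark lists with a list test adjusted p under 0.05, and oxidative phosphorylation has a negative median and a dot in 12 of the 13 comparisons.

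Overlaps between comparisons were counted to ask whether tumours, EVPs and TNF acted on shared genes, with Fisher's exact test (two-sided) in each direction, adjusted over 15 pairs of comparisons. B16F10 tumours and B16F10 explant EVPs raised 111 genes in common, where independent lists would share 40.5 (adjusted p = 2.8e-23), and lowered 60, where 23.9 would be shared, among 12054 genes in the authors' deposited tables. Coro1a, an actin regulator gene of leukocytes, stood at 1.21 ± 0.24 and 0.72 ± 0.17 log2, and Atp5c1 at −0.63 ± 0.12 and −0.27 ± 0.07, in these deposited tables of the authors. K7M2 tumours and K7M2 explant EVPs raised 67 genes in common against 26.1 for independent lists and lowered 146 against 54.3 (adjusted p = 9.17e-34) in the authors' deposited tables. Il1b was higher in both at 1.56 ± 0.27 and 1.49 ± 0.31, and Ndufv1 lower at −0.59 ± 0.09 and −0.32 ± 0.08, in the authors' deposited tables. The B16F10 and K7M2 tumours raised 469 genes in common against 138 and lowered 317 against 105 in the authors' deposited tables, with Apcs at 2.68 ± 0.20 and 3.19 ± 0.09. Explant EVPs of B16F10 and K7M2 raised 22 genes in common against 8.86 (adjusted p = 7.5e-05) and lowered 26 against 12.2 in the authors' deposited tables. TNF in hepatocytes and B16F10 explant EVPs in livers raised 255 genes in common against 131 and lowered 99 against 75.0 (adjusted p = 0.00331), while 136 moved in opposite directions against 199 for independent lists in the authors' deposited tables. Tgfb1 stood at 1.13 ± 0.13 and 0.97 ± 0.18 and Csf1r at 0.76 ± 0.11 and 0.98 ± 0.22 in these deposited tables of the authors. Csf1r is on the Kupffer cell list, whose members mostly fell in the TNF-treated cultures and mostly rose after B16F10 explant EVPs. TNF and K7M2 explant EVPs lowered 138 genes in common against 53.9 (adjusted p = 2.94e-29) and raised 42 against 31.5 (0.0442) in the authors' deposited tables. Pdk2 stood at −1.69 ± 0.08 and −0.51 ± 0.22 and Pdk4 at 1.47 ± 0.10 and 1.04 ± 0.50 in these deposited tables of the authors. With every gene included in the adjustment, genes that moved the same way numbered 121 in place of 213 for K7M2 tumours and EVPs (26.0 in place of 80.4 for independent lists), 17 in place of 48 for both explant EVPs (4.77 in place of 21.1), and 101 in place of 180 for TNF and K7M2 EVPs (27.3 in place of 85.4) in the authors' deposited tables. The values for independent lists fell more than the counts because fewer genes passed among a larger number of genes. Genes named beside these overlaps were chosen after their values were seen. Genes are not independent of each other, so these Fisher p-values overstate the evidence.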

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

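The hepatocyte share test below was chosen after the result it bears on had been seen, and the tests of a difference between effects were chosen after the data had been seen. The numbers of genes called in B16F1-Tb and B16F10-Tb had been seen before the predictions on mouse number and annotation were written. The differences in the next 3 paragraphs stand out because the effects of 2 treatments differed in a test of the difference itself, and the last 3 paragraphs weigh other patterns.

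Effects of B16F10 and B16F1 tumours differed for 1132 genes and 8 gene lists. In the panel, B16F10-Tb minus B16F1-Tb was −3.42 log2 for Lcn2, −3.03 for the alarmin gene S100a8, 1.98 for Isg15, 1.56 for Cyp7a1, 1.17 for the fatty acid synthase gene Fasn and 1.24 for the lipid droplet gene Plin2, with effects recovered from the authors' deposited tables. The clock genes Nr1d1 and Dbp differed by 1.43 and 1.47 in the same comparison, from the authors' deposited tables.

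Between 4T1 and 67NR tumours 3928 genes and 14 lists differed. The acute phase genes Saa2 and Orm2 had effects higher in 4T1-Tb by 4.37 and 2.92 log2, the chemokine gene Cxcl1 by 1.03 and Isg15 by 0.68, from the authors' deposited tables. Effects were lower in 4T1-Tb for the bile acid genes Cyp7a1 (−1.87) and Cyp8b1 (−0.70), for Cyp2e1 (−1.0), for the fatty acid genes Cpt1a (−1.14), Ppara (−0.76) and Cd36 (−0.71), for Plin2 (−0.91) and for Dbp (−1.20), from the authors' deposited tables.

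Explant and cell-line EVPs differed for 279 genes and 8 lists with B16F10, and for 2 genes and 1 list with K7M2. Exomeres and Exo-S differed for 46 genes and 16 lists, exomeres and Exo-L for 27 genes and 20 lists, and Exo-S and Exo-L for 5 genes and 13 lists. The gene counts of the K7M2 pair and of the class pairs are too low, because the covariance from their shared controls was left out. With the folds as deposited by the authors, 7 of the 8 lists still differed for B16F10 and B16F1 tumours, 4 of 8 for B16F10 EVPs, 0 of 1 for K7M2 EVPs in the limma list test, and 13 of 16, 18 of 20 and 12 of 13 for the class pairs in that order. In the panel Isg15 differed between exomeres and Exo-S, by −1.27 log2 from the authors' deposited tables.

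Oxidative phosphorylation genes were lower after B16F10 explant EVPs, at a median of −0.18 log2 in the authors' deposited table. A lower share of hepatocytes would lower hepatocyte identity genes at least as much, but their median lay 0.149 log2 above (95% bootstrap interval 0.0307 to 0.234). The interval resampled genes, not mice, so it leaves out variation among the livers. The folds compared were the shrunken ones. Of 10000 random lists matched on transcript length, GC content and base mean, 0 percent (0.0) had so low a median. Their medians centred on −0.0309 log2, and the lowest lay at −0.0811. The matched genes were drawn independently, so any family of genes regulated together can lie outside these lists. The test therefore cannot decide on transcript length and GC content. Ribosomal protein genes, with short transcripts as well, had been seen to fall in 25 of 73 cases before that test was written. Their median of −0.11 log2 and that of proteasome subunit genes (−0.14; 15 of 38 fell) in the authors' deposited table also lay below that lowest value, although no lists were matched to these families. The fall was thus not confined to respiratory chain genes. RNA quality and day of dissection were not recorded, so a direct effect of the EVPs on mitochondrial gene expression may be one of several open explanations.

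More genes passed the threshold in B16F1-Tb than in B16F10-Tb, although B16F1 is the less metastatic line. More mice per group would not give this alone, since 3581 genes passed against 1475 on 12385 common genes after the B16F1-Tb scores were scaled from 5 mice to 3. A larger annotation would not either, with 5346 against 1384 on the 15489 genes that have a p-value in both tables. The spread (standard deviation) of effects beyond their error was 0.700 log2 in B16F1-Tb and 0.342 in B16F10-Tb, from the authors' deposited tables. That measure gives weight to extreme genes, and the median size of effect differed less, at 0.268 and 0.206 log2. The median standard error was 0.131 in B16F1-Tb and 0.191 in B16F10-Tb. How much this lower precision in B16F10-Tb adds to its smaller count was not tested. Tumour size, blood loss, handling and the separate experiments stay open, and tumour line and experiment cannot be told apart.

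Interferon-stimulated genes rose after each of the 3 particle classes of B16F10. Control levels were estimated from the base means and the recovered effects, scaled to the summed base means of each comparison. By these estimates low levels in the PBS-10 controls are argued against, because PBS-10 lay above both other sets of C57BL/6 controls for EVPs. The median difference was 0.227 log2 over PBS-8 (bootstrap bounds 0.155 to 0.305) and 0.483 over PBS-6 (0.364 to 0.564). It was 0.133 over the tumour controls PBS-4 (0.0730 to 0.204), against a rise of 1.48 after Exo-S in the authors' deposited table. These controls belong to separate experiments, normalised separately, so shifts between experiments are part of the differences. These bounds resampled genes, not mice, so they leave out variation among the livers. PBS-1 was not compared. The list differed between exomeres and Exo-S (adjusted p = 2.57e-22), a difference in which the shared controls cancel, so it does not tell how much they add to the rise common to the 3 classes. Endotoxin or other contaminants of a preparation could raise such genes too, and no file allows a test of that. A response of liver cells to the particles themselves therefore remains a hypothesis.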

How the results depend on the processing

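Tests with other settings of the differences and of the lists, and the base mean limit, were chosen after the data had been seen; the adjustment over every gene and the 0.01 threshold were planned, although the tests of differences and lists, to which the former was applied too, were not. No paired analysis was possible because the deposited tables hold no per-sample values, and for the same reason a second count-based test, another size-factor scaling, leaving out each replicate, a replicate term and another pseudocount were not run. With a base mean of at least 50, all 13 counts of changed genes stayed within 1.5 times the reported ones, and without a filter 18 results did while 9 did not, leaving out the number of named genes, which is fixed by rule. The base mean limit turned an excess of rises into an excess of falls in 4T1-Tb (2558 up, 3132 down) and B16F1-Tb (2275 up, 2750 down). It did so by less in K7M2-Tb (1879 up, 1976 down) and B16F10-Tb (658 up, 664 down). Without a filter the counts fell to 275 for K7M2-TE-EVPs and 347 for B16F10-CL-EVPs, the differing genes to 148 (B16F10 TE and CL), 1 (K7M2 TE and CL), 30 (exomeres and Exo-S) and 12 (exomeres and Exo-L), and the shared genes to 121 (K7M2 tumour and EVPs; 26.0 for independent lists), 17 (both TE-EVPs; 4.77) and 101 (TNF and K7M2-TE-EVPs; 27.3), because more genes entered the adjustment. With recovered errors multiplied by 5/4, differing genes numbered 353 for the B16F10 and B16F1 tumours, 0 for B16F10 TE and CL (normal test; 2167 at an unadjusted p under 0.05 as reported), 1 for K7M2 TE and CL, 1 and 1 for exomeres against Exo-S and Exo-L, and 0 for Exo-S and Exo-L (648 unadjusted). With the deposited folds, 8 differed for B16F10 TE and CL, 1 for K7M2 TE and CL and 11 for Exo-S and Exo-L, and with a correlation of 0.5 between effects 29 (K7M2), 348, 797 and 249 (the 3 class pairs) did. At an adjusted p under 0.01 in both, shared genes numbered 46 (16.2 for independent lists), 56 (17.3), 442 (103), 5 (2.65), 141 (67.0) and 50 (19.5) for the 6 overlaps in the order reported, a stricter threshold by construction. The list tests gave 196 calls without a filter, 213 with a preset correlation of 0.01 and 224 on ranks, against 172. The cause of the changes with the deposited folds was not tested. Depth is unknown, and no count or floor can be given for genes of low base mean.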

Other observations

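The tests on hypoxia and on BMP signalling in this part were written before their results were seen. Smad7 and Atoh8 of the BMP list had met the rule for named genes in some comparison, so single values of theirs may have been seen. The gene families of the first paragraphs were chosen after the data had been seen and have no list test. Families outside the fixed lists moved in several comparisons, counted here from the authors' deposited tables. MHC class II genes, which present antigen to T cells, rose in 5 of 9 cases after exomeres, 6 of 9 after Exo-S and 9 of 9 after Exo-L, with medians of 1.42, 1.35 and 1.99 log2 in the authors' deposited tables. After B16F10-TE-EVPs and after B16F10-CL-EVPs 0 of 8 rose or fell, with medians of 0.14 and 0.13 log2 there. Among the B16F10 EVP groups the rise was thus seen only in the experiment with PBS-10. In K7M2-Tb and 4T1-Tb 5 of 8 rose each, and in B16F1-Tb 3 of 9 fell in the authors' deposited tables. Complement genes, which the liver secretes, rose in 13 of 16 cases and 1 fell in K7M2-Tb (median 1.43), 13 of 17 rose and 3 fell in 4T1-Tb (median 0.99), and 11 of 16 rose and 1 fell in 67NR-Tb (median 0.51) in the authors' deposited tables. TNF-treated hepatocytes went the other way, with 10 of 15 complement genes lower in the authors' deposited table. Of 11 coagulation factor genes 10 were lower there as well. In K7M2-Tb 7 of the 11 rose and 1 fell, but in 4T1-Tb 1 rose and 5 fell in the authors' deposited tables. In 67NR-Tb 2 rose and 4 fell.

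Proteasome subunit genes fell in 32 of 38 cases in B16F1-Tb and 1 rose (median −0.35), and 15 of 38 fell after B16F10-TE-EVPs, while 18 of 38 rose in TNF-treated hepatocytes in the authors' deposited tables. Ribosomal protein genes rose in 44 of 75 cases in B16F1-Tb and 1 fell (median 0.24), and 25 of 69 fell in 67NR-Tb (median −0.17) in the authors' deposited tables. All 19 major urinary protein genes tested in B16F1-Tb fell, with a median of −3.94 log2 in the authors' deposited table, although these genes share reads.

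In B16F1-Tb the hepcidin genes fell and erythroid markers rose together with Fgf23. A hypoxia response in the liver was put forward as a hypothesis and tested on 23 hypoxia targets, leaving out genes whose values had been seen, such as Apln, Stc1 and Ndufa4l2. In the authors' deposited table for B16F1-Tb 18 of the 23 rose and 1 fell, with a median of 0.96 log2 (list test adjusted p = 1.58e-06 over 13 comparisons). The list fell in TNF-treated hepatocytes, with 18 of 23 lower and 1 higher in the authors' deposited table (adjusted p = 8.22e-05), and passed in none of the other 11 comparisons. This is consistent with low oxygen in these livers, which anaemia or blood loss could bring about, but neither was measured and hypoxia targets also respond to other signals.

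Lower BMP and SMAD target expression, a readout of the main inducer of hepcidin, was the other hypothesis. Of Id1, Id2, Id3, Smad6, Smad7 and Atoh8, 3 of 6 members fell and none rose in B16F1-Tb, with a median of −0.40 log2 in the authors' deposited table, fewer than the 4 asked for beforehand and more than the 1 that would have argued against it. The same genes fell in 4 of 6 cases in K7M2-Tb, where Hamp2 was lower as well, in the authors' deposited table. Hamp is not reported here for K7M2-Tb, so that fall concerns Hamp2 alone. Such falls occurred elsewhere too, with 3 of 6 lower after B16F10-CL-EVPs, 3 lower and 1 higher in TNF-treated hepatocytes, 2 lower in 67NR-Tb, and 2 lower and 1 higher in 4T1-Tb in the authors' deposited tables. In B16F10-Tb, where Hamp2 stood at −0.72 ± 0.24 and Hamp at −0.26 ± 0.21 (adjusted p = 0.48), 1 of the 6 genes rose and none fell in the authors' deposited table. This hypothesis on the fall of hepcidin in B16F1-Tb therefore stays open.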
